A study of Mus musculus with 52 samples.

How the data were processed

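DNaseI hypersensitivity was measured by the authors in mouse cell lines and tissues. Per the series' design text, nuclei were digested with DNaseI, fragments released by a pair of cleavages were isolated, and their ends were sequenced as 36 bp reads on Illumina instruments. Uniquely mapping reads were placed on the mouse genome with bowtie, per the same text, and the build was mm9, per the submitters' processing notes; the version of bowtie is not given in the sources used here. Zones of raised sensitivity (hotspots) were called with Hotspot version 5.2, and peaks within zones of a 1% false discovery rate with lmax version 1.1, per the labels. Lists were deposited per library, not pooled over libraries of a sample.

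In the hotspot lists, the deposited score is the hotspot's own value from the authors' caller, at least 2 in every list. In the peak lists, the deposited signal is the authors' tag density in a 150 bp window moved in 20 bp steps, a whole number of at least 2. Both lists hold a −log10 p deposited by the authors, with a ceiling of 324. All of these are values of single peaks from the authors and were used only to describe, rank or filter peaks within a list. Every peak overlapped a hotspot of its library by at least 1 bp, and the hotspot lists went further down, with 29.9 to 73.1% of hotspots at or above the lowest −log10 p deposited for a peak of the same library. Absence of a hotspot was therefore used as a strict form of absence. The tag totals of libraries are not given in the sources used here, and no interval that needs them was computed.

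Samples were grouped by their labels. The 30 files of 15 libraries from 8 samples were used; the other samples of the series are not analysed here, among them the untreated ZhBTc4 cells, the parental line of the H1-null cells and liver without the deletion. Peaks of all libraries were merged where they shared at least 1 bp, which gave 593136 regions with a median length of 170 bp and a maximum of 1630 bp. A library had a region open when a peak of its list overlapped it by at least 1 bp.

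Similarity was the Jaccard index, tested by rearranging libraries over samples 100000 times (two-sided). The 6 mG/ER libraries were compared over all 15 pairings. A region was called changed when both libraries of one group had a peak and neither library of the other had a peak or hotspot, and the counts were set beside those of the other partings of the same 4 libraries. Shares of regions found in another sample were compared between opened and closed regions by flipping signs over 20 chromosomes (1 to 19 and X) 100000 times, two-sided. The slope of the share of mG/ER peaks inside hotspots of another sample was tested exactly over 90 arrangements, with untreated cells taken as 0 h. Deletions were looked for as runs of regions missing in a sample, against 10000 shuffles within chromosomes. The Benjamini-Hochberg method was used for adjustment, over the samples compared over lists and samples or over lists and directions, at a threshold of 0.05.

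Genes came from the GENCODE vM1 annotation of NCBIM37, whose chromosome lengths hold all peaks of the files. The 15 gene lists were fixed before the data were examined, and 81.8 to 100% of each list's symbols matched a protein-coding gene. H1f0 is annotated there as a pseudogene and was given for its position only. A gene was open in a sample when every library had a peak within 2500 bp of one of its transcription starts, and Fisher's exact test compared each list with all other protein-coding genes. Changed regions were assigned to the nearest protein-coding start within 50 kb, and their share near a list was compared with that near other genes by Fisher's exact test over regions, which are not independent replicates. Regions were placed within 1 kb of any transcript start, in an exon, in an intron or between genes, in that order. Named regions follow a rule set at the same time: per comparison, the 10 regions with the highest smaller within-list percentile of tag density over the libraries with the peak, the 3 longest runs of missing regions, the 3 windows of 1 Mb with most changes, all globin and linker histone genes, and the erythroid and pluripotency genes with most changed regions. A few items that this rule takes are not reported here. Progenitor, retinal and trophectoderm genes, the 12 regions missing in H1-null cells and the chromosome 7 stretch were chosen after their values were seen.

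Alternatives were the strongest 50% of each list, lists of equal length (102826 peaks), overlap of at least 50% both ways, absence judged from peaks alone, presence judged by hotspots, each library left out, libraries of the same number taken as pairs, hotspots or peaks as the overlap, regions over 10 kb from a region shared by all, at least 4 of 6 mG/ER libraries, absence of a peak as missing, and promoter windows of 1000 and 5000 bp. Where peak lists were cut, the hotspot lists were left whole. Further alternatives were added after the data were seen and are named as such. GC content and motifs were read from 150 bp around the middle of each region of the reference sequence, on both strands, for 23 consensus motifs, and shares were compared within 5 GC classes weighted equally.

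The tests were first tried on simulated data. Of 200 opened and 200 closed regions planted among 100000 simulated regions of the untreated and 48 h mG/ER libraries, 184 and 176 were recovered with 5 calls each where nothing was planted, and the highest other parting gave 13. The simulated libraries were alike in depth and nearly free of noise, whereas the other partings of the real libraries gave 264 and 553. The simulation therefore checks the calculation and gives no rate of recovery or of false calls for these data. Without an effect, the sign-flip test passed in 7.00% of 200 simulations, and the run test in 3.00% of 200 over 20000 regions. For the sign-flip test, random values stood in for the differences of the 20 chromosomes, and no opened or closed regions were simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.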

Results

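Chromatin accessibility was mapped in mouse cells and tissues by DNaseI digestion of nuclei followed by sequencing of the ends of the released fragments, so that a peak marks a short stretch of open, mostly regulatory DNA. The series has 52 samples, and the peak and hotspot lists of 8 of them, 15 libraries in all, were analysed here. Erythroid cells were represented by mG/ER cells, an erythroleukaemia line carrying a fusion of the erythroid transcription factor GATA-1 to the oestrogen receptor, which matures on estradiol. They were profiled untreated and after 24 h and 48 h of estradiol. Liver of embryonic day 14.5, then the main site of red cell formation, came from animals labelled homozygous for a deletion of the β-globin locus control region, the distal enhancer cluster of the β-globin genes. Whole brain of embryonic day 18.5 and retina of postnatal day 1 stood for neural tissue. Of 2 embryonic stem (ES) lines, ZhBTc4 had been kept for 24 h in 100 ng/ml doxycycline, which in this line switches off the pluripotency factor Oct4, and the other was labelled as lacking the linker histones H1c, H1d and H1e and is called H1-null below. Each sample had 2 libraries except retina, which had 1. Lists held between 102826 and 178466 peaks per library (median 132546), and the wider hotspots covered 66.9 to 119 Mb, or 2.52 to 4.48% of the genome. Numbers of sequenced tags per library are not given in the sources used here, so depth is unknown and a longer list may come from a deeper library. The labels do not say whether libraries of 1 sample came from separate cultures or animals, so every p-value measures only the spread between these libraries, chromosomes or regions.

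Libraries grouped by cell type. Peak sets of the same sample shared most of their regions, mG/ER cells at all times lay closest to one another and next to fetal liver, the ES lines lay close to each other, and brain lay closest to retina. Over the 593136 regions in which any library had a peak, the Jaccard index (regions shared by a pair of libraries divided by regions in either) averaged 0.607 within samples (0.551 to 0.661, 7 pairs) and 0.268 between samples (98 pairs). The difference of 0.339 was larger than that of any rearrangement drawn, with a two-sided permutation p of 1e-05, the smallest that 100000 rearrangements can give. mG/ER cells shared a mean index of 0.336 with fetal liver untreated, 0.354 at 24 h and 0.367 at 48 h, against 0.140, 0.141 and 0.143 with brain. The ES lines shared 0.416 with each other (0.389 to 0.445), below the 0.551 and 0.598 of their own library pairs. Peaks on the X chromosome took 3.57% and 3.55% of the lists of untreated mG/ER cells, 3.25% to 3.49% of those after estradiol, and 1.76% to 1.95% in every other library.

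**Figure D1:**
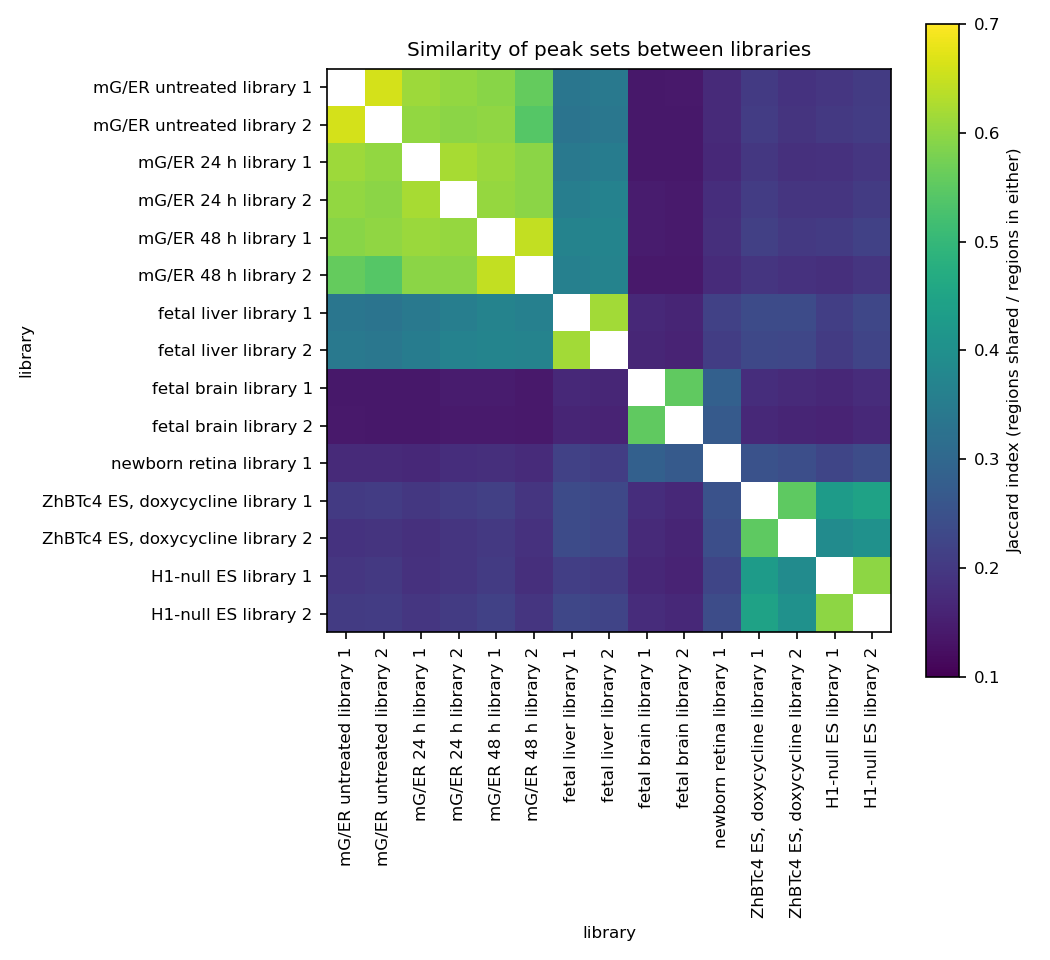
Jaccard index of the peak sets of each pair of the 15 libraries (colour; both axes list the libraries, the diagonal is left blank). Same-sample pairs lie between 0.551 and 0.661, and the mG/ER and liver blocks and the ES block stand out from the rest.

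A small part of the mG/ER landscape differed between untreated cells and cells given estradiol for 48 h. From untreated cells to 48 h, 2317 regions opened and 3236 closed, while 72386 stayed open in all 4 libraries. A region counted as opened when both later libraries had a peak and neither earlier library had a peak or even a hotspot there, and as closed in the reverse case. Closing came first: by 24 h 1496 regions had closed and 310 had opened, and between 24 h and 48 h 1108 opened and 543 closed. Of the 1496 regions lost at 24 h, 1245 had no peak in either library at 48 h. Both times were set against the same untreated libraries, whose lists were longer (mean 125963 peaks, against 115143 at 24 h and 115579 at 48 h). Lasting closing was therefore not told apart from regions called only in longer lists. Most opened regions were called only at 48 h: 1703 of the 2317 had no peak in either library at 24 h. Hotspots at 24 h did not count there, so weaker opening by 24 h was not told apart from later opening. The 4 libraries of the 48 h comparison can be parted in other ways that mix the samples, and those gave 264 and 553 changed regions in all, against 5553 for the real one. The totals were 1806 against 327 and 354 at 24 h, and 1651 against 513 and 412 between 24 h and 48 h. The smaller counts stood out little by themselves: the 310 regions opened by 24 h compare with 290 and 236 in 1 direction of the mixed partings, and the 543 closed between 24 h and 48 h with 454 in 1 direction of such a parting. With 2 libraries against 2, chance alone gives the real parting the highest count in 33.3% of cases, so no p is given for these counts.

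The balance between opening and closing depended on the lists. With every peak list limited to its strongest 102826 peaks and the hotspot lists left whole, opened regions outnumbered closed ones at 48 h, with 1654 against 951 (other partings 38 and 50 in all), and in the strongest 50% of each list with 269 against 49. At 24 h closing still led, with 285 closed and 122 opened regions in lists of equal length. Counts grew where a group kept 1 library, because less was then asked of it. Without untreated library 1, untreated library 2, 48 h library 1 and 48 h library 2 in turn, 3277, 4321, 6425 and 7095 regions opened by 48 h and 11676, 8208, 8720 and 4719 closed, so that opening led once 48 h library 2 was left out. For the change by 24 h, 587, 1152, 2434 and 3822 regions opened and 7042, 4614, 4279 and 3304 closed without untreated library 1, untreated library 2, 24 h library 1 and 24 h library 2, the last of which turned the order. Between 24 h and 48 h, 2767, 2179, 5078 and 5489 regions opened and 4283, 6323, 2452 and 1134 closed without 24 h library 1, 24 h library 2, 48 h library 1 and 48 h library 2, and closing led without either 24 h library.

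**Figure D2:**
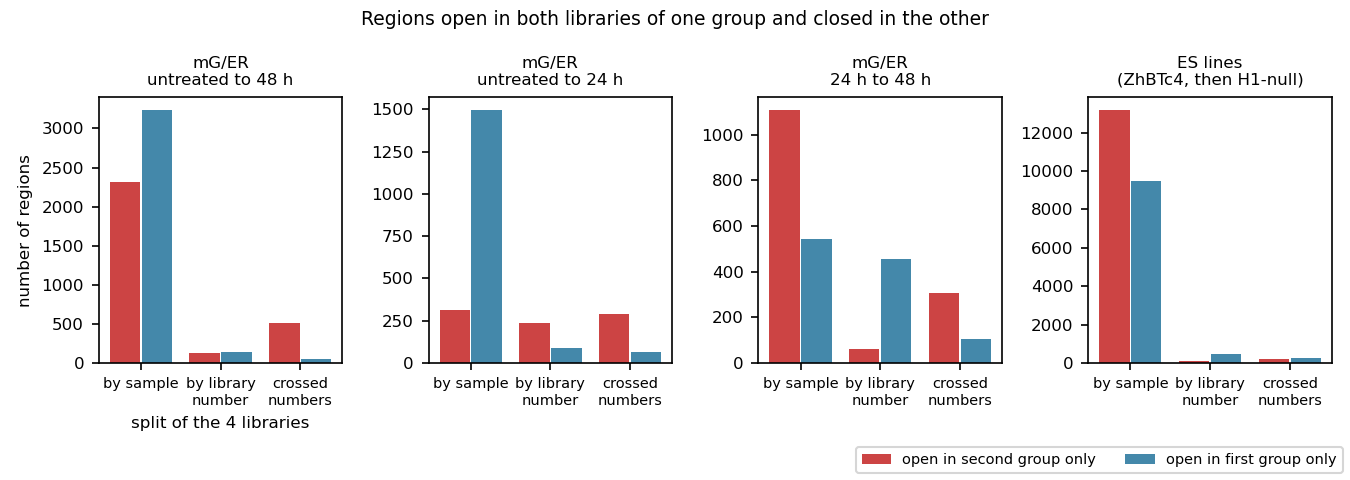
Number of regions open in both libraries of one group and closed in the other (vertical axis), for the 4 libraries of each comparison parted by sample and in the 2 other ways. Red bars are regions open only in the second group (the later time, or the H1-null line) and blue bars those open only in the first; parting by sample gave 5553 regions at 48 h, against 264 and 553 otherwise.

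Similarity of the mG/ER libraries followed time. Libraries of the same time shared a mean index of 0.643, libraries 24 h apart 0.602, and untreated and 48 h libraries 0.573. Of the 15 ways to pair the 6 libraries, pairing by time gave the highest difference between paired and unpaired libraries, 0.0502 against 0.0244 for the next. The exact permutation p was 0.0667, the smallest this design can give, so the test could not pass 0.05.

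Promoters of the listed erythroid genes had peaks before estradiol was added. Most of these genes met the same call in ES cells, retina and brain too, as given below, so the call does not mark erythroid cells by itself. All 27 erythroid genes that could be matched, among them the transcription factors Gata1, Klf1 and Tal1 and the haem synthesis gene Alas2, had a peak within 2500 bp of a transcription start in untreated mG/ER cells, at 24 h, at 48 h and in fetal liver. Changes near them were few: 8 regions opened and 3 closed, with 355 regions within reach, or 2.25% against 1.99% near other genes for opening (Fisher's exact test, adjusted p = 1) and 0.845% against 2.22% for closing (exact p = 0.0994, adjusted 0.990). Neither passed, and so few regions leave the difference in closing unresolved. Ank1, which encodes the membrane skeleton protein ankyrin, had 2 opened regions. Zfpm1 (FOG-1, a GATA-1 cofactor), Slc4a1 (the red cell anion exchanger) and Bcl2l1 (an inhibitor of apoptosis) had 1 opened region each. The membrane skeleton genes Epb4.1 and Spnb1 had 1 opened and 1 closed region each, and Lmo2, an adaptor of erythroid transcription complexes, had 1 closed region. Near early progenitor genes, 5 of 234 regions closed (2.14%, against 2.21% near other genes) and 2 opened (0.855% against 1.99%), and neither passed (Fisher's exact test, adjusted p = 1 each). Of these genes, Kit (the stem cell factor receptor), Myb and Cd34 had 1 closed region each, and Gata2 and Runx1 had 1 opened and 1 closed region each. Of the globin genes, Hbb-b1 (adult β-globin) and Hbq1a each gained 1 region, and Hbb-b2, Hbb-bh1, Hbb-y, Hba-a1, Hba-a2, Hba-x and Hbq1b had no changed region assigned. Only absence against presence counts here, so a change in strength at a region open throughout is not seen. At the start of Hbb-b1 the tag density was 149 and 267 untreated and 1292 and 665 at 48 h. At the start of Hbb-b2 (110962361 to 110962570) it was 142 and 206 untreated and 1006 and 636 at 48 h. Beyond the other end of Hbb-b2, at 110960081 to 110960270, it was 138 and 245, then 115 and 66. Such values were not tested, since depth is unknown.

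Only 1 of the 15 gene lists, that of retinal genes, passed the test for changed regions between untreated and 48 h mG/ER cells. Of 72 open regions near retinal genes, 8 closed (11.1%, against 2.21% near other genes; Fisher's exact test, adjusted p = 0.00578). Prdm1, a transcriptional repressor that also acts in blood cells, accounted for 3 of them, and Otx2, Pou4f1, Pou4f2, Onecut1 and Opn1sw for 1 each. Against random genes with as many regions nearby, a resampling test gave an adjusted p of 0.0330 (10000 draws, a comparison added after the data were seen). The primitive endoderm list, with 2 of 13 regions closed, reached an unadjusted exact p of 0.0324 and did not pass. The call depended on untreated library 1, without which 11 of 80 regions closed (13.8%, against 7.16% near other genes) and the list did not pass (adjusted Fisher's exact p = 0.298). The count was 18, 12 and 9 without untreated library 2, 48 h library 1 and 48 h library 2, with an adjusted exact p of 4.01e-05, 0.0180 and 0.0173, and 4 with lists of equal length (adjusted exact p = 0.0264).

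The strongest opened regions lay mostly inside or near genes not on the erythroid list. Ranked by the lower of the within-list percentiles of tag density in both 48 h libraries, the first lay in an exon, 3.63 kb upstream of the nearest start of Cd82, which encodes a tetraspanin (chromosome 2, 93296361 to 93296570, mm9), with a tag density of 474 and 227 in the 48 h libraries, and it had a peak in both 24 h libraries too. Tag densities are the authors' own values of single peaks. Next came an intergenic region on chromosome 8 (15519821 to 15519990) nearest to Myom2, 401 kb away, and intronic regions nearest to Mtss1l (chromosome 8, 113213981 to 113214190), Igf2r, the receptor that clears insulin-like growth factor 2 (chromosome 17, 12910441 to 12910690), and Tmem56 (chromosome 3, 120979821 to 120980030). The others of the first 10 lay nearest to Gm10430, Serp2, Suv420h2 (a histone methyltransferase, 0.750 kb from its start), Dusp10 (a phosphatase of MAP kinases) and Bbc3 (PUMA, a promoter of apoptosis). Apart from those nearest to Myom2 and Gm10430, all of the first 10 had a peak in both 24 h libraries. The strongest closed regions lay nearest to Zcchc2 (chromosome 1, 107805821 to 107805990), Frk, a tyrosine kinase (chromosome 10, 34228541 to 34228770), 1700019M22Rik, Gm6741, Epb4.1l3, Lilra5, Anks1b, Sox5 and Podxl. Opened regions were densest between 72000001 and 73000000 of chromosome 8 (13 regions), around Chst1 between 92000001 and 93000000 of chromosome 2 (12, of which 8 nearest to Chst1) and between 105000001 and 106000000 of chromosome 7 (12). Closed regions were densest at 48000001 to 49000000 of chromosome 6 (10, of which 4 nearest to Krba1) and at 92000001 to 93000000 and 138000001 to 139000000 of chromosome 5 (8 each). Relative to regions that stayed open, the chromosome with the highest share of closed regions was X, at 1.67 times its share of kept regions.

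Opened and closed regions lay in different places. Introns held 59.9% of opened and 37.3% of closed regions, and 718 of the 2317 opened and 1788 of the 3236 closed regions were intergenic. Both were mostly distal, with 5.44% and 4.91% within 1 kb of a transcript start, against 28.2% of regions that stayed open. The intronic share was higher in opened regions on 20 of 20 chromosomes (difference 22.6 percentage points; two-sided permutation p from sign flips over chromosomes 1e-05, the smallest possible; this test was added after the data were seen). Without 48 h library 1 the difference fell to 9.11 points, with opening higher on 20 chromosomes and the same permutation p of 1e-05.

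Regions that opened were found in fetal liver more often than regions that closed. A peak in both liver libraries covered 14.5% of regions opened by 48 h and 4.82% of closed ones, a difference of 9.68 percentage points, higher on 19 of 20 chromosomes (two-sided permutation p from sign flips 1e-05, the smallest possible, adjusted p = 5e-05). Both shares lay far below the 59.4% of regions that stayed open. With liver hotspots in place of peaks, the shares were 26.5% and 14.5%. The direction rested on 48 h library 1: without it the liver difference turned to -1.75 points (adjusted permutation p = 0.0316). That library had the fewest hotspots of the 15 libraries (141264), of which 73.1% reached the lowest −log10 p of its peaks, the highest such share. By coverage both 48 h libraries stood apart, with hotspots over 66.9 and 70.6 Mb against at least 81.5 Mb in every other library, so the condition that a closed region lacks a hotspot was met more easily at 48 h. The liver difference was 15.5 points without untreated library 2 and 5.83 without 48 h library 2 (permutation p = 1e-05 each, the smallest possible). Closed regions were found slightly more often than opened ones in brain (difference -1.40 points, adjusted permutation p = 0.00308), in ZhBTc4 cells (-1.55 points, adjusted permutation p = 0.00527) and in H1-null cells (-2.83 points, adjusted permutation p = 0.00148), and in retina the difference of 0.198 points did not pass (adjusted permutation p = 0.936). These smaller differences depended on single libraries. Without untreated library 1, brain gave -0.0997 (adjusted permutation p = 0.535), ZhBTc4 0.784 (adjusted permutation p = 0.327), H1-null -0.704 (adjusted permutation p = 0.219) and retina 1.48 (adjusted permutation p = 0.0547). Without untreated library 2, brain gave 0.807 (adjusted permutation p = 0.0469), ZhBTc4 2.80 (adjusted permutation p = 0.0006), H1-null 1.45 (adjusted permutation p = 0.123) and retina 3.41 (adjusted permutation p = 2.5e-05). Without 48 h library 1, brain gave -4.81, retina -7.46, ZhBTc4 -11.1 and H1-null -15.0 (permutation p = 1e-05 each, the smallest possible). Without 48 h library 2, brain gave -0.657 and no longer passed (adjusted permutation p = 0.0564), and ZhBTc4 gave -0.919 (adjusted permutation p = 0.0136). With lists of equal length, brain (-0.500 points), ZhBTc4 (-0.760) and H1-null (-1.68) no longer passed and retina did (1.36 points, unadjusted permutation p = 0.0113). With hotspots in place of peaks, brain, ZhBTc4 and H1-null cells did not pass either (adjusted permutation p = 0.219, 0.327 and 0.0587).

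**Figure D3:**
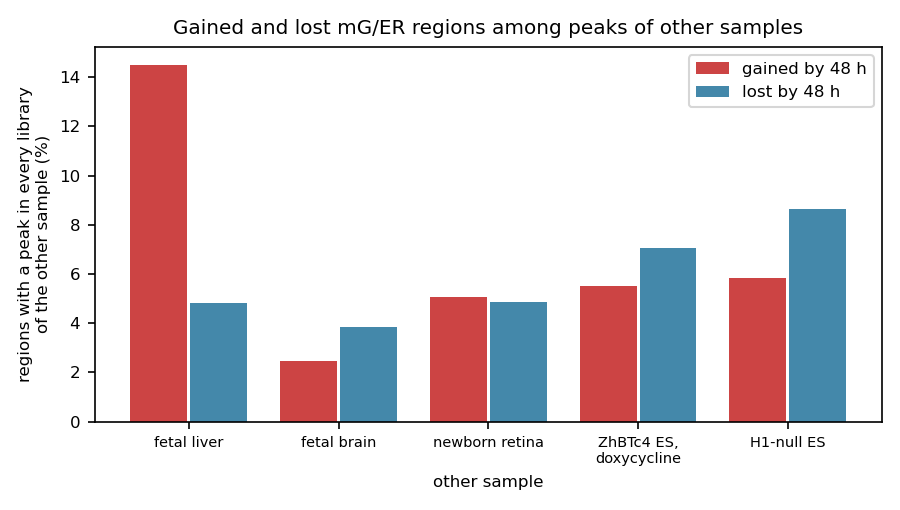
Share of mG/ER regions opened (red) and closed (blue) by 48 h that had a peak in every library of each other sample (vertical axis, %). Liver shows 14.5% against 4.82%, and the other 4 samples differ by 2.83 percentage points or less.

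For the whole mG/ER peak list, the test of a move towards another sample had little power, and no slope passed. The share of peaks inside liver hotspots averaged 61.1% ± 1.88 untreated (SD, n = 2), 66.0% ± 2.45 at 24 h and 65.4% ± 2.10 at 48 h, a slope of 2.14 percentage points per 24 h (two-sided exact permutation p = 0.156, adjusted over 5 samples 0.639). The smallest possible exact p was 0.0222, or 0.111 after adjustment for a move towards 1 sample alone, so such a move could not pass 0.05. With lists of equal length the liver slope was 0.283 points per 24 h (exact permutation p = 0.733). The Jaccard index with liver lay between 0.331 and 0.342 for untreated libraries and between 0.362 and 0.370 at 48 h, but with lists of equal length, a comparison added after the data were seen, the ranges overlapped (0.349 to 0.366 and 0.363 to 0.393). Slopes towards brain, retina and the ES lines were between 0.389 and 0.877 points per 24 h and did not pass either (adjusted exact permutation p 0.639 to 0.778).

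Many regions of mG/ER cells were also open in fetal liver. Of 66112 regions open in all 6 mG/ER libraries, 62.2% had a peak in both liver libraries and 11.8% had no hotspot in either. Without the regions open in all 15 libraries, the share with a peak in both liver libraries was 47.1% of 47299. The labelled deletion of the β-globin locus control region was looked for as a stretch of erythroid regions missing in liver. On chromosome 7, upstream of the embryonic β-globin gene Hbb-y, 10 regions were open in all 6 mG/ER libraries between 111007701 and 111025910 (18.2 kb), and 9 of them had no liver hotspot, the most missing regions within 25 kb anywhere. A permutation test of that count, added after the data were seen, gave p = 0.0140, and the highest of 1000 shuffles was 10. In the gene cluster, 9 of 12 such regions had peaks in both liver libraries, all nearest to Hbb-b2 or Hbb-b1, and 1 had no hotspot. Hbb-y had no peak within 2500 bp of its start in either liver library. Liver without the deletion is not analysed here. Inside the missing stretch 1 region, 111009481 to 111009710, kept a peak in both liver libraries, at percentiles 97.9 and 97.8 of their lists. By the measure fixed beforehand, consecutive missing regions, the longest stretches lay elsewhere, with 17 regions between 110905981 and 118647290 of the X chromosome (nearest gene Dach2) and 13 between 83249141 and 89842950 of X. Runs of 12 lay on X (133697301 to 135743990), chromosome 1 (109542221 to 113530950) and chromosome 14 (91858521 to 97029690). These 5 runs were longer than any in the shuffles, whose maximum was 11 (permutation p = 1e-04 for the longest, the smallest possible). Liver lacked 23.6% of the 2128 erythroid regions of the X chromosome and 11.4% of those of autosomes, but X peaks took 3.25% to 3.57% of the mG/ER lists and 1.87% and 1.95% of the liver lists, so the runs on X do not tell DNA missing in liver from more X regions being called in mG/ER cells.

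**Figure D4:**
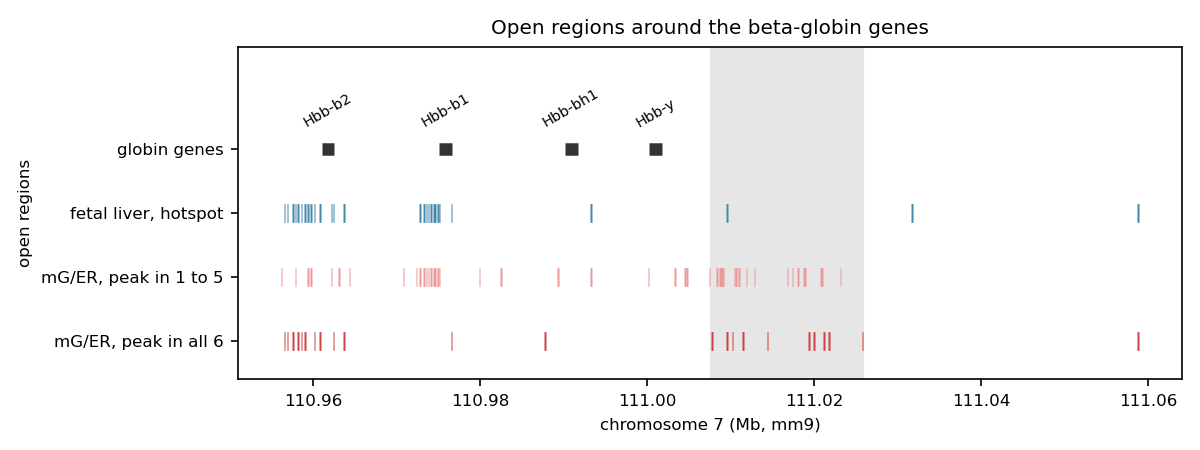
Open regions around the β-globin genes on chromosome 7 (horizontal axis in Mb, mm9). Black boxes are genes, blue ticks regions with a hotspot in a liver library, and red and pale ticks regions with a peak in all 6 or in fewer mG/ER libraries; 9 of the 10 red ticks in the grey stretch, 111007701 to 111025910, have no blue partner.

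H1-null cells lacked regions at the genes named in their label. Of 19089 regions open in all 13 other libraries, 12 had no hotspot in either H1-null library, none of them next to another (longest run 1, permutation p = 1). These 12 included the start of Hist1h1c (chromosome 13, 23830601 to 23830810), which encodes H1c, and the start of Hist1h1d (chromosome 13, 23646801 to 23647070), which encodes H1d. Within 2500 bp of its start Hist1h1c had 3 regions, and Hist1h1d 2, without a hotspot in H1-null cells although all 13 other libraries had one. At Hist1h1e, which encodes H1e, 1 region inside the gene (23713821 to 23714050) did so, while the start itself (23714261 to 23714550) had peaks in both H1-null libraries. Regions inside Hist1h1c (23831421 to 23831770) and Hist1h1d (23647921 to 23648150) had peaks in all 15 libraries. No such region was found at Hist1h1a, Hist1h1b, Hist1h1t, H1f0, H1fx or H1foo. The other 10 missing regions lay nearest to Hbp1, Trim36, Cand1, Jak2, Fam65b, Mbp, Daf2, Usp3, Mapk14 and Nfam1.

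The ES lines shared the pluripotency landscape and differed at many distal sites. Of the regions open in both libraries of a line, 73930 were open in both lines, 13179 were open in H1-null cells and closed in ZhBTc4 cells, and 9460 the reverse. Other partings of the 4 libraries gave 583 and 483 regions in all. With lists of equal length the counts were 4044 and 3296, with 10 and 6 in the other partings. H1-null only regions numbered 22293 without ZhBTc4 library 1, 22317 without H1-null library 1 and 30068 without H1-null library 2, and ZhBTc4 only regions 23230 and 20177 without ZhBTc4 library 1 and library 2. The lines differ in origin, genotype and treatment at once, and their matched controls are not analysed here, so no difference can be assigned to doxycycline or to the loss of H1.

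All 21 pluripotency genes had a peak near a start in both ES lines, among them Pou5f1 (Oct4), Nanog and Sox2, against 4 of 21 in mG/ER cells, below other genes (adjusted Fisher's exact p = 0.00534 untreated). The call was not confined to ES cells: Sox2, Klf4, Klf2, Klf5, Tbx3, Tcfcp2l1, Sall4 and Prdm14 met it in liver, brain and retina too. Nanog, Zfp42, Dppa2, Dppa4, Dppa5a and Tcl1 had no promoter peak in those tissues. Single regions near the pluripotency genes differed between the lines in both directions. Esrrb, an orphan nuclear receptor of ES cells, had 3 regions open only in H1-null cells and 2 only in ZhBTc4 cells, and Tbx3 had 2 and 4. Zfp42 (Rex1) had 2 and 2, Tcl1 2 and 1, Sall4 and Prdm14 2 and 0, Klf2 0 and 2, and Pou5f1 and Sox2 1 and 1. Of trophectoderm genes, Tcfap2c had 1 region open only in H1-null and 4 only in ZhBTc4 cells, Cdx2, the regulator of trophectoderm fate, 0 and 2, and Eomes 2 and 0. None of the 15 gene lists passed the test of changed regions in either direction (lowest adjusted p by Fisher's exact test 0.313). At an unadjusted exact p under 0.05, 2 tests passed, both of the neuronal list, with fewer changed regions than near other genes (3.25% against 6.63%, exact p = 0.0209, and 1.81% against 4.80%, exact p = 0.0157). For linker histone genes, 3 of 20 regions were open only in ZhBTc4 cells (adjusted Fisher's exact p = 0.442).

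The strongest H1-null only region lay between genes, 36.5 kb from Eef1a1, a translation elongation factor gene (chromosome 9, 78373401 to 78373550), with a tag density of 311 and 235. It was followed by regions nearest to Ier2, an immediate early gene (chromosome 8, 87177061 to 87177390), Epha2, an ephrin receptor (chromosome 4, 140840501 to 140840710), Strn, Zmat4, Ston1, Egln3, Wrn, Msln and Ctgf. The strongest ZhBTc4 only region lay 66.4 kb from Tas2r119, a taste receptor gene (chromosome 15, 32040541 to 32040710), with 317 and 422. It was followed by 2 regions near Vmn2r-ps100, and by regions nearest to Iffo2, Trim63, Hist1h1c, Gm17430, Sh3bp4, Klf3 and Tnnt3. H1-null only regions were densest on chromosome 14, with 42 between 87000001 and 88000000, 26 of them nearest to Diap3, and none open only in ZhBTc4 cells there. Chromosome 17 had 38 between 79000001 and 80000000 and 33 between 84000001 and 85000000. ZhBTc4 only regions were densest on chromosome 11 (25 between 116000001 and 117000000), chromosome 13 (22 between 52000001 and 53000000) and chromosome 14 (22 between 121000001 and 122000000, 10 nearest to Farp1). Chromosome 14 held 2.29 times its share of shared regions among H1-null only regions, the highest ratio of chromosomes 1 to 19 and X.

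Among samples with 2 libraries, brain and the ES lines held the most regions of their own. Regions with a peak in every library of a sample and no hotspot in any other kind of cell numbered 23768 in brain, 16203 in retina (1 library, with no replicate check, so less was asked of it), 26535 in H1-null, 19283 in ZhBTc4 and 3894 in liver cells, and 11326, 7273 and 8077 in untreated, 24 h and 48 h mG/ER cells. The ES lines count as 1 kind of cell here, and so do the mG/ER times: 8323 of the ES regions were open in both lines, and 4373 of the mG/ER regions in all 6 libraries. Apart from these counts, 5741 regions were open in brain and retina alone and 4124 in mG/ER cells and liver alone. Brain regions were distal, at a median of 90.9 kb from a protein-coding start, against 19.3 kb in liver. In all 15 libraries 18813 regions were open (3.17%), 54.6% of them within 1 kb of a transcript start. Specific counts rose where 1 library was left out: 39471 and 37756 in brain, 6411 and 7130 in liver, and 33596 and 34939 in ZhBTc4 cells without library 1 and library 2, 47618 without H1-null library 2, 19662 and 16216 in untreated mG/ER cells without library 1 and library 2, where 1 library is asked for as in retina, 11918 and 15447 at 24 h, and 12935 and 14688 at 48 h, again without library 1 and library 2.

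The strongest brain regions lay nearest to Gm9808 (chromosome 12, 52219021 to 52219210), Tmem182, Nell1, Kif16b, Plcb4, Mfap3, Gm16833, Fam174a, Kctd16 and Mad2l2. The strongest retina regions lay in an intron of Ston2 (chromosome 12, 92934321 to 92934470, tag density 572), 529 kb from Sox2, a neural progenitor factor, and nearest to Chrm3, a muscarinic receptor gene, Sdk2, which encodes an adhesion molecule of retinal synapses, 5930403N24Rik, Bccip, Pde3a, Cdk1, Gm1840 and Tcf7l2. The strongest liver regions lay nearest to Gm10152 (chromosome 7, 151972561 to 151972750), Gm12394, Osbpl1a, Alg9, Mki67, Tnfrsf21, Slc38a9, BC049635, Sfrp4 and Spock1. Brain and retina shared a Jaccard index of 0.277 (0.270 to 0.284), the highest of either tissue with another sample. Retina shared 0.247 and 0.233 with the ZhBTc4 and H1-null lines. The mean index of brain with retina exceeded their mean index with the other samples by 0.106.

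Promoters of several lists were open more often in some cell types than others. Of 120 tests of a list in a sample, 34 passed (Fisher's exact test, adjusted over all 120). In liver, 17 of 18 hepatocyte genes had a promoter peak (adjusted exact p = 0.0130), against 6 of 18 in untreated and 48 h mG/ER cells, beside the full erythroid list. Most hepatocyte genes also met the call in brain, in retina and in each ES line, while Alb and Afp had a promoter peak only in liver. All 32 neuronal genes had one in brain (adjusted exact p = 2.38e-05) and in retina (adjusted exact p = 0.000259), but also 30 of 32 in ZhBTc4 and H1-null cells, where the list passed as well (adjusted exact p = 0.0134 and 0.0203), so that the call was not confined to neural tissue. It reached 9 of 32 in mG/ER cells, below other genes (adjusted exact p = 0.00778 untreated). Retinal genes reached 21 of 22 in retina (adjusted exact p = 0.0323) and lay below other genes in mG/ER cells at 24 h and 48 h (6 of 22, adjusted exact p = 0.0323 each). Globin promoters were open in 8 of 9 genes in untreated mG/ER cells and 7 of 9 in liver, against 1 of 9 in brain (adjusted exact p = 0.0108), 2 of 9 in retina and H1-null cells (adjusted exact p = 0.0165 and 0.0130), and 3 of 9 in ZhBTc4 cells. All 15 trophectoderm genes were open in ZhBTc4 cells and in retina (adjusted exact p = 0.0323 each), and 14 of 15 in H1-null cells, which did not pass. Housekeeping genes were open in 22 of 22 in every sample and passed in all 8. Promoters of erythroid genes were also open in 17 of 27 in brain, 20 of 27 in retina, 24 of 27 in ZhBTc4 cells (adjusted exact p = 0.139) and 25 of 27 in H1-null cells (adjusted exact p = 0.0566), none of which passed. Lists of primitive endoderm, glial, early progenitor, macrophage and myeloid, fibroblast and linker histone genes passed in no sample, and endothelial genes passed only as below other genes in mG/ER cells at 24 h (2 of 11, adjusted exact p = 0.0497). Several calls depended on the window, and 26 passed at 1000, 2500 and 5000 bp alike. Retinal genes in retina (adjusted exact p = 0.0650 at 1000 and 0.0746 at 5000 bp), trophectoderm genes in retina (0.278 and 0.0539) and endothelial genes at 24 h (0.0862 and 0.224) passed at neither other window. At 5000 bp, globin genes in brain, retina and H1-null cells (adjusted exact p = 0.0862, 0.130 and 0.0993), trophectoderm genes in ZhBTc4 cells (0.0803) and neuronal genes in H1-null cells (0.0631) no longer passed. Lists that newly passed at 1000 bp were retinal genes in untreated mG/ER cells (adjusted exact p = 0.0107), hepatocyte genes in untreated and 48 h mG/ER cells (0.0159 each) and brain (0.0237), and macrophage and myeloid genes in brain (0.0181), all below other genes. At 5000 bp, erythroid genes in ZhBTc4 and H1-null cells newly passed as above other genes (26 of 27 each, adjusted exact p = 0.0310 and 0.0429), and primitive endoderm genes at 24 h and 48 h (0.0310 each) and fibroblast genes in liver (0.0233) as below them.

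**Figure D5:**
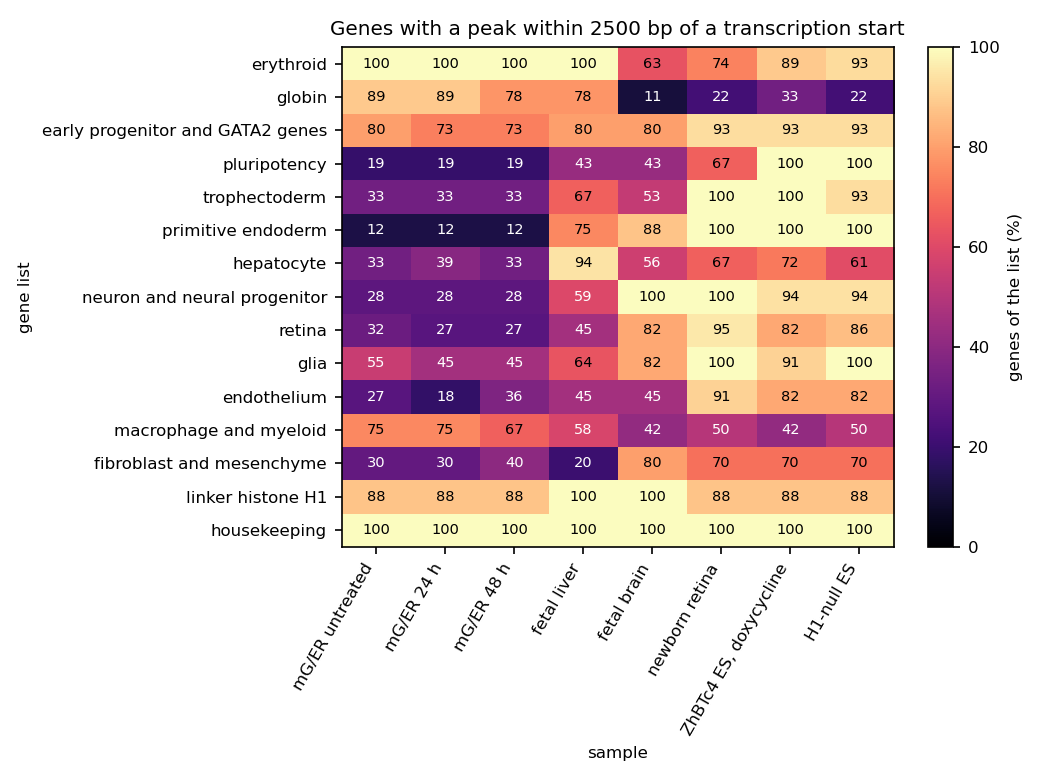
Share of the genes of each list (rows) with a peak within 2500 bp of a transcription start in every library of a sample (columns), in percent, with the value in each cell. The erythroid list reaches 100% in mG/ER cells and liver, the pluripotency list 100% in both ES lines and 19% in mG/ER cells.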

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

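Leaving out single libraries for specific regions, missing stretches and slopes, the count within 25 kb, the similarity to liver with lists of equal length, the draws of random genes and the checks of the retinal list were chosen only after the data were seen. Over all alternatives, 142 recomputed values kept their direction and call or moved little, 104 counts or differences moved further, 15 turned direction, 10 no longer passed and 2 newly passed, judged by p adjusted within each setting wherever the result itself was adjusted. The separation of samples by similarity, the higher share of opened regions in liver with all 4 libraries, the longest stretches missing in liver and the regions shared by all 15 libraries were among those that kept their direction and call, or moved little, in every setting other than a left-out library. Promoter tests that passed numbered 36 at 1000 bp and 31 at 5000 bp, against 34, with 26 in common. The depth of the libraries is unknown, which limits every count of absent regions, and 2 libraries per sample, or 1 for retina, limit every statement on spread. Except where the construction of a setting is named, the cause was not tested.

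In the strongest 50% of each list, which holds fewer peaks by construction, there were 269 opened and 49 closed by 48 h, 2 and 8 by 24 h, and 30 and 7 between 24 h and 48 h, 2675 H1-null only and 1701 ZhBTc4 only regions. Specific regions numbered 3260 (untreated), 1735 (24 h), 2249 (48 h), 876 (liver), 8802 (brain), 3384 (retina), 6083 (ZhBTc4) and 8539 (H1-null). Opened minus closed shares were 1.49 points in brain, 3.72 in ZhBTc4 and 0.379 in H1-null cells, all turned in direction. Lists of equal length, again shorter by construction, gave 951 closed regions by 48 h, 122 opened and 285 closed by 24 h, 616 and 153 between 24 h and 48 h, 4044 H1-null only and 3296 ZhBTc4 only regions, and 14932 (brain), 8821 (retina), 9643 (ZhBTc4) and 11533 (H1-null) specific regions. Opened minus closed shares no longer passed in brain (-0.500), ZhBTc4 (-0.760) and H1-null cells (-1.68) and newly passed in retina (1.36). The slopes over time, none of which passed, turned to -0.432 points per 24 h towards brain, -0.510 towards retina, -0.569 towards ZhBTc4 and -0.864 towards H1-null cells, and the slope towards liver was 0.283. The rise of the Jaccard index with liver from untreated to 48 h was 0.0214, against 0.0309 with the lists as deposited. With an overlap of at least 50% both ways, the retina difference turned to -1.36 points, and the index of brain with retina exceeded that with the other samples by 0.0954.

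With absence judged from peaks alone, a looser criterion by construction, there were 8402 opened and 11337 closed by 48 h, 3701 and 9525 by 24 h, and 7056 and 4745 between 24 h and 48 h, 31503 H1-null only and 21976 ZhBTc4 only regions, and 27080 (untreated), 19923 (24 h), 21567 (48 h), 10143 (liver), 40302 (brain), 40580 (retina), 39184 (ZhBTc4) and 50273 (H1-null) specific regions. With presence judged by hotspots there were 6827 opened and 15438 closed by 48 h, 6288 and 10337 by 24 h, and 5397 and 9189 between 24 h and 48 h, 30101 H1-null only and 30889 ZhBTc4 only regions, and 17234 (untreated), 13294 (24 h), 12457 (liver), 47944 (brain), 55390 (retina) and 34550 (ZhBTc4) specific regions. Closing then led between 24 h and 48 h, and ZhBTc4 only regions outnumbered H1-null only ones. With hotspots of the other sample as the overlap, opened minus closed shares no longer passed in brain (-0.571), ZhBTc4 (-0.0925) and H1-null cells (-1.50, adjusted permutation p = 0.0587).

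Without 1 library in turn, which by construction asks less of its group, 3277 to 7095 regions opened and 4719 to 11676 closed by 48 h, 587 to 3822 and 3304 to 7042 by 24 h, and 2179 to 5489 and 1134 to 6323 between 24 h and 48 h. H1-null only regions numbered 17489 to 30068 and ZhBTc4 only regions 13242 to 23230. Specific regions numbered 16216 to 19662 (untreated), 11918 to 15447 (24 h), 12935 to 14688 (48 h), 6411 to 7130 (liver), 37756 to 39471 (brain), 33596 to 34939 (ZhBTc4) and 38587 to 47618 (H1-null). Opened minus closed shares ranged from -1.75 to 15.5 points in liver, -4.81 to 0.807 in brain, -7.46 to 3.41 in retina, -11.1 to 2.80 in ZhBTc4 and -15.0 to 1.45 in H1-null cells. Direction turned without 48 h library 1 in liver (-1.75) and retina (-7.46), without untreated library 1 in ZhBTc4 (0.784), and without untreated library 2 in brain (0.807), ZhBTc4 (2.80) and H1-null cells (1.45). The call ended without untreated library 1 in brain (-0.0997) and H1-null cells (-0.704) and without 48 h library 2 in brain (-0.657), and retina newly passed without untreated library 2 (3.41). Closed regions near retinal genes numbered 9 to 18, and the call ended without untreated library 1 (11, adjusted Fisher's exact p = 0.298). The slope towards H1-null cells ranged from -0.257 to 0.738 and was negative without untreated library 2.

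Taking libraries of the same number as pairs (a replicate block, with changes counted within each pair and averaged) gave 10316 opened and 16621 closed by 48 h, 5539 and 10930 by 24 h, and 8824 and 9057 between 24 h and 48 h, since each pair then has 1 library per time. Deviations of same-numbered libraries correlated by 0.0117 between untreated and 24 h, -0.0235 between untreated and 48 h and -0.00238 between 24 h and 48 h, so the numbers were not taken to pair the libraries.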

Other observations

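All 23 motifs and the 9 comparisons of regions in which they were counted were chosen after the numbers of changed and specific regions had been seen, and the 4 comparisons of liver only regions after their motif shares had been seen too. Of the tests of explanations, those of GATA motifs, GC content, whole chromosomes and copies of a sequence were set down before their result, and those of list length, the segment of chromosome 14, DNA of other cells and hotspot length were chosen only after the result was seen.

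Sequence motifs parted the opened and closed regions of mG/ER cells. A GATA motif, the binding sequence of GATA-1, lay in 61.2% of opened, 41.4% of closed and 36.2% of kept regions. At equal GC the order of the last pair turned: closed regions held fewer GATA motifs than kept ones (difference -7.21 percentage points, higher on only 2 of 20 chromosomes, permutation p = 3e-05), and opened regions held more (22.7 points). The PU.1 motif, bound by a myeloid factor that opposes GATA-1, lay in 13.4% of closed and 1.21% of opened regions (difference at equal GC -12.6 percentage points, lower on 20 of 20 chromosomes). The NF-E2 motif, bound by an erythroid and megakaryocytic factor, lay in 4.23% of opened and 0.0927% of closed regions (4.29 points), and the wider AP-1 motif in 12.0% and 4.73% (7.42 points). Each had a permutation p of 1e-05 from sign flips over chromosomes, the smallest possible, and an adjusted p of 4.6e-05 over 23 motifs. Left-out libraries moved these values in part: without 48 h library 1 the difference was 1.53 points for NF-E2 and 1.85 for AP-1, and without untreated library 1 and library 2 it was -7.98 and -7.90 for PU.1. The KLF motif was not more frequent in opened regions at equal GC. Its share differed by -1.58 points from that of closed regions (adjusted permutation p from sign flips 0.0733) and by -3.02 points from that of kept regions (adjusted permutation p = 0.0120). Regions open in mG/ER cells and liver alone had a GATA motif in 81.6%. Regions open in all mG/ER libraries alone, and so at every time, had a GATA motif in 63.4%, near the share of opened regions. Their median GC was lower (44.7% against 48.7% in opened regions), and no comparison of these sets at equal GC was made. Regions open in all mG/ER libraries alone had a PU.1 motif in 15.7%, against 1.13% of liver only regions.

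Motifs of known lineage factors also marked the other sets. Liver only regions held the HNF4 motif in 15.4%, the FOXA motif in 10.3% and the CEBP motif in 6.01%, all motifs of hepatocyte factors. At equal GC these shares exceeded those of regions open only in brain, only in retina, only in both ES lines or only in all mG/ER libraries by 10.4 to 11.7 points for HNF4, 4.1 to 7.76 for FOXA and 4.70 to 5.38 for CEBP. Retina only regions held the motif of CRX and OTX, photoreceptor factors, in 14.2% against 3.64% in brain only regions (11.6 points at equal GC), and brain only regions more often held the neural E-box (36.9% against 31.1%, -9.64 points), RFX (-3.93 points) and MEF2 (-1.49 points) motifs. Each of these differences had a permutation p of 1e-05, the smallest possible, with 1 retina library. Between the ES lines, the OCT motif lay in 4.79% of H1-null only and 0.328% of ZhBTc4 only regions (4.34 points), the KLF motif in 16.2% and 9.77% (7.79 points), the GATA motif in 18.5% and 24.7% (-8.06 points), and the TFAP2 motif, of a trophoblast factor family, in 3.51% and 16.6% (-12.3 points). All 4 held on 20 of 20 chromosomes (permutation p = 1e-05, the smallest possible). The motifs of SOX and ESRR, also families of pluripotency factors, went the other way from OCT (-3.33 and -1.90 points, lower on 19 and 20 chromosomes, the same permutation p of 1e-05). Without H1-null library 1, the OCT difference fell to 2.92 points, without H1-null library 2 the KLF difference was 4.21, without ZhBTc4 library 1 the TFAP2 difference was -8.18, and without ZhBTc4 library 2 the SOX difference was -0.791. By their label, ZhBTc4 cells were given doxycycline for 24 h to repress Oct4; Oct4 itself was not measured and no untreated ZhBTc4 cells are analysed here, so the line and the treatment were not told apart. The CTCF motif lay in 13.9% of regions shared by all libraries and in at most 0.958% of regions opened or closed in mG/ER cells.

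Changed regions in mG/ER cells at 48 h outnumbered those of the other partings 52.1 times with peak lists of equal length. This argues against the length of the peak lists as the whole cause. Hotspot lists, which also decide absence, were not cut, and their mean coverage was 90.4 Mb untreated and 68.8 Mb at 48 h. Unequal hotspot lists therefore stay open as an explanation. No chromosome held more than 1.67 times its share of kept regions, which argues against a change of whole chromosomes as the whole cause. GC-dependent bias of the libraries stays open: the median GC of opened regions was 4.67 points above that of closed ones, between the bounds set down for this test, and without 48 h library 1 the order turned (44.7% in opened and 46.0% in closed regions). GATA factor activity, the biological explanation the design gives, predicted more GATA motifs in opened regions than in closed ones. The difference was 24.9 points with GC classes weighted equally (17.2 to 37.7 over the classes), so part of the opening may come from the induced GATA-1 fusion. A high share does not mark induction by itself, since 63.4% of regions open in all mG/ER libraries alone held the motif, untreated cells included. That share was not matched for GC. The size of the difference between opened and closed regions depended on 1 library. Without 48 h library 1 it was 7.31 points, and in 1 GC class it was -5.38. No vehicle-treated culture of the same age is analysed here, so time in culture remains untested.

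Regions open in one ES line and closed in the other outnumbered those of other partings 734 times with peak lists of equal length. This argues against the length of the peak lists, while the hotspot lists were again not cut. Copy number of whole chromosomes was not decided, since the highest ratio, 2.29 on chromosome 14, lay between the bounds set down. On that chromosome 11 of 13 bins of 10 Mb (84.6%) held more H1-null only regions per shared region than the median bin of other autosomes, and the segment between 60 and 100 Mb, picked from these bins, held 514 of its 959 H1-null only regions, against 35 ZhBTc4 only regions. Within the ZhBTc4 lists, the 180 regions of the segment open in all libraries differed in median percentile from such regions elsewhere on autosomes by -11.6 points (-10.1 and -13.1 in the 2 libraries), within the H1-null lists by -0.389, and within the other lists by -4.51 to 0.833. The difference between the lines was -11.2 points, so a lower copy number in the ZhBTc4 line is a candidate explanation for an excess among these 514 of 13179 regions. It is no candidate for all 514, since the segment had 535 shared regions and the median bin of other autosomes held 0.188 H1-null only regions per shared region. Line, genotype and treatment remain confounded for the others.

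The peak kept in liver inside the missing stretch of chromosome 7, 111009481 to 111009710, lies 7.73 kb upstream of Hbb-y, holds NF-E2 and GATA motifs, and is open in all 6 mG/ER and all 4 ES libraries. Another copy of the sequence in the reference genome was not found, with 0% of its 195 words of 36 bases present elsewhere. Only uniquely mapping reads were placed, so this outcome was largely fixed beforehand and decides nothing about another copy. A copy absent from the reference would not be seen. The liver hotspot there was 67 bp long in both libraries, against 3586 to 4780 bp in mG/ER cells and 373 to 996 bp in the ES libraries. At most 0.0971% of hotspots of equally ranked liver peaks were as short (median 1897 and 2279 bp). DNA of cells without the deletion would give a hotspot of ordinary length, and even among equally ranked hotspots that fit the 2270 bp between the missing regions on both sides, at most 0.196% were as short, which argues against such cells as the source. Tags from a short stretch of DNA alone, such as a fragment left or added when the deletion was made, remain a candidate explanation. The short hotspot prompted this explanation and so does not test it, and no test of its origin was possible with the lists.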
